A study of Trichoderma atroviride with 90 samples.

How the data were processed

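The series holds RNA sequencing of Trichoderma atroviride mycelium frozen in liquid nitrogen. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit, version 2. The authors deposited a single table of expected counts, that is estimated counts before any normalisation, for 12019 transcript models of 11787 genes in 90 libraries. Per the submitters' processing notes FastQC, Trimmomatic, HISAT2, edgeR and limma were used, with no versions or settings, and the genome build and the counting tool are not given in the sources used here. The values read as unnormalised counts that need not be whole: 6.41% of the values were fractional, in 3037 models, and 82.64% of the fractional values ended in 0.5 as decimal part. A value split in such parts is what sharing of reads between models gives, so levels of closely similar or overlapping models are uncertain. Because the counts were not whole, the edgeR test planned for raw counts was run on values rounded to whole numbers. Of the models, 50 had no count in any library, and 204 genes had 2 or more models.

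Column names were matched to samples through the library codes. For 54 libraries the wording and the bracketed library code of the title named different strains and preys, and the source name and genotype fields followed the wording. Each set of 3 libraries entered the fit as its own group, so the 30 groups are the same under both readings, and only the comparisons differ. The library-code reading is given first, because the code is unique to a library. For the reading by wording only counts of transcripts are given. No library was assigned or moved by its values.

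The identifiers did not pair with names: 0 of them matched the 13312 entries of the gene table of assembly ASM2064779v1 used here. Gene list tests planned by product name (with an alternative in their inter-gene correlation) and the level of the mutated genes were therefore not run, and transcripts are given by identifier. Transcripts were named by a fixed rule, in the form it set for identifiers without names: among called transcripts whose groups did not overlap and whose mean was at least 5 CPM in the higher group, the 2 with the largest rise and the 2 with the largest fall per comparison. For the differences between responses, groups were not required to separate. A few transcripts outside the rule are said to have been chosen after their values were seen.

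Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Models with low counts were removed with filterByExpr, which left 10843 models and 99.99% of the reads and removed 1176 models. Libraries were scaled by TMM. A single quasi-likelihood model with robust estimation was fitted to all 90 libraries in 30 groups, with 60 residual degrees of freedom and no replicate block. The median biological coefficient of variation was 23.4%. A call was a Benjamini-Hochberg adjusted p below 0.05 with a log2 fold change of at least 1 in size. Each log2 fold change is given with a standard error, its size divided by the square root of the quasi-likelihood F statistic. Such a standard error restates the test and is not a separate estimate of precision. CPM are counts scaled to a common library size, computed here from the deposited counts, with TMM-scaled library sizes for group means and with plain library totals for the per-library checks of Tatro_011104-T1, Tatro_001008-T1 and Tatro_008395-T1. Where every library of the lower group had no count, a fold is given as a bound against a floor of 3 counts over the group. With 1 to 3 counts it is a ratio with an exact Poisson 95% interval. The fitted fold changes of such transcripts depend on the prior count and are no bounds.

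The design, the tests, the naming rule, the order of the readings and most alternatives were fixed before the data were examined. The alternatives were size factors of the RLE kind, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit limited to the groups compared, the replicate number as a block, and leaving out replicate 1, 2 or 3 of every group. Chosen after seeing the data were: the strain transcripts, the summing of transcript models per gene, fits without each control library alone, without 3 odd libraries or without dcr2 with Alternaria before and at contact (the WT groups of the same prey and stages, or in the stage comparisons the whole series, then left the averages too), and 11 further comparisons by the library code. In fits that leave a group with fewer libraries its spread is taken from all groups. An adjusted p that DESeq2 did not give counted as no call.

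Replicates were compared before averaging. Over 90 pairs of libraries of the same group the chi-square per gene was at least 5.32 with a median of 37.8, and r of log2 CPM was at least 0.957 with a median of 0.983, so no library repeated another of its group within sampling noise. Libraries of different groups were not compared in this way. Same-numbered libraries were checked for shared deviations from their group means. Over 435 pairs of groups the median correlation was 0.054 for the same number and -0.027 for other numbers. Of the 11 comparisons of 3 against 3 libraries, the numbers paired the samples only for the dcr2 and WT controls, by correlations of 0.398, 0.109 and 0.141 that come from the data and not from the labels.

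The count test was tested on simulated data for the comparison of dcr2 with WT controls with 10789 models, of which 200 were changed. It recovered 31 of 67 changed 2-fold (46.3%), 65 of 67 changed 4-fold (97.0%) and 66 of 66 changed 8-fold (100.0%), and 4 of its 166 calls (2.4%) were false. The simulated counts followed the fitted model, with a spread per transcript shared by all groups. The WT control replicates correlated less well (r 0.957 to 0.980) than the median pair (0.983). The share of false calls in the real comparisons may therefore be higher. A call needs a fitted log2 fold change of at least 1, so transcripts changed exactly 2-fold lie at that threshold, and their share of calls does not measure what 3 libraries can detect. Library totals ran from 0.936 M to 19.01 M counts, and the library of 0.936 M gives the least precise values. Overlaps of calls are given beside the number that independent lists would share, and for comparisons with the same controls beside 20 simulations without effects.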

Results

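Transcript abundance was measured by RNA sequencing in mycelium of Trichoderma atroviride, a soil fungus that attacks other fungi and is used in biological control. The wild type (WT), a dcr2 mutant and an ago3 mutant were grown alone or facing a prey fungus on potato dextrose agar in darkness at 27 °C. Dicer proteins cut double-stranded RNA into small RNAs and Argonaute proteins bind these, and the strains were studied as mutants of such components of RNA interference. The preys were the plant pathogens Rhizoctonia solani of anastomosis groups AG2 and AG5 and Alternaria alternata. Each strain was sampled with each prey before contact (BC), at contact (C) and after contact (AC), with 3 libraries per group, which gave 30 groups and 90 libraries including 9 libraries of strains grown alone. The 9 libraries grown alone carried no stage label, so differences from them may also reflect the age of the cultures. The question was how components of RNA interference act on the attack on prey fungi. Library totals ran from 0.936 M to 19.01 M estimated counts (M, mega) with a median of 8.26 M, and the next lowest library held 5.39 M. The shallow library was replicate 2 of the ago3 mutant coded with AG5 after contact. Median totals were 8.22 M for WT, 8.62 M for dcr2 and 7.89 M for ago3. Nothing in the labels said that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

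The sample labels contradicted themselves for 54 of the 90 libraries. Each title holds a description in words and a bracketed library code, and in 6 of the 9 series of strain and prey the strain and prey changed places between them: a title worded as WT with AG5, for example, carried the code of dcr2 with AG2. The 36 libraries whose fields matched were WT with AG2, dcr2 with AG5, ago3 with Alternaria and the 3 controls. Stage and replicate never conflicted. Both readings of the 54 libraries are given, the library code first. Transcript models for the dcr2 and ago3 genes themselves were not identified here, because the identifiers had no match in the gene table used, so the mutated genes could not be used to check the labels.

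Transcripts that separated the strains in the 36 matching libraries were therefore followed into the other 54. No transcript met the criterion fixed beforehand (below 1 CPM in one strain and above 10 CPM in the others, or the reverse), and the transcripts with the widest margin were taken after the counts were seen. Tatro_011104-T1 stood at 2.05 ± 0.75 CPM (SD, n = 12) in dcr2, 361.7 ± 185.9 CPM in WT and 208.7 ± 86.3 CPM in ago3. Among the conflicting libraries, those coded dcr2 held 4.40 ± 5.28 CPM (n = 18) of Tatro_011104-T1, whereas those worded dcr2 held 173.9 ± 114.1 CPM (n = 18). Tatro_001008-T1 stood at 33.7 ± 11.7 CPM in ago3, 2.14 ± 2.10 CPM in WT and 1.13 ± 0.62 CPM in dcr2 (n = 12 each). Conflicting libraries coded ago3 held 36.7 ± 14.1 CPM of Tatro_001008-T1, whereas those worded ago3 held 2.09 ± 1.68 CPM (n = 18 each). With the midpoints of the matching libraries as borders, Tatro_011104-T1 contradicted the library code in 1 and the wording in 35 of the 54 libraries. Tatro_001008-T1 contradicted the code in 0 and the wording in 36 of the 54, as the plot of both transcripts by library shows. Of the 18 conflicting libraries worded dcr2, 0 held the dcr2 level of Tatro_011104-T1, against 17 of the 18 coded dcr2. Of the 18 worded ago3, 0 held the ago3 level of Tatro_001008-T1, against 18 of the 18 coded ago3. These levels argue against the strain in the wording for these libraries. They checked the readings and assigned no library to a group.

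**Figure D1:**
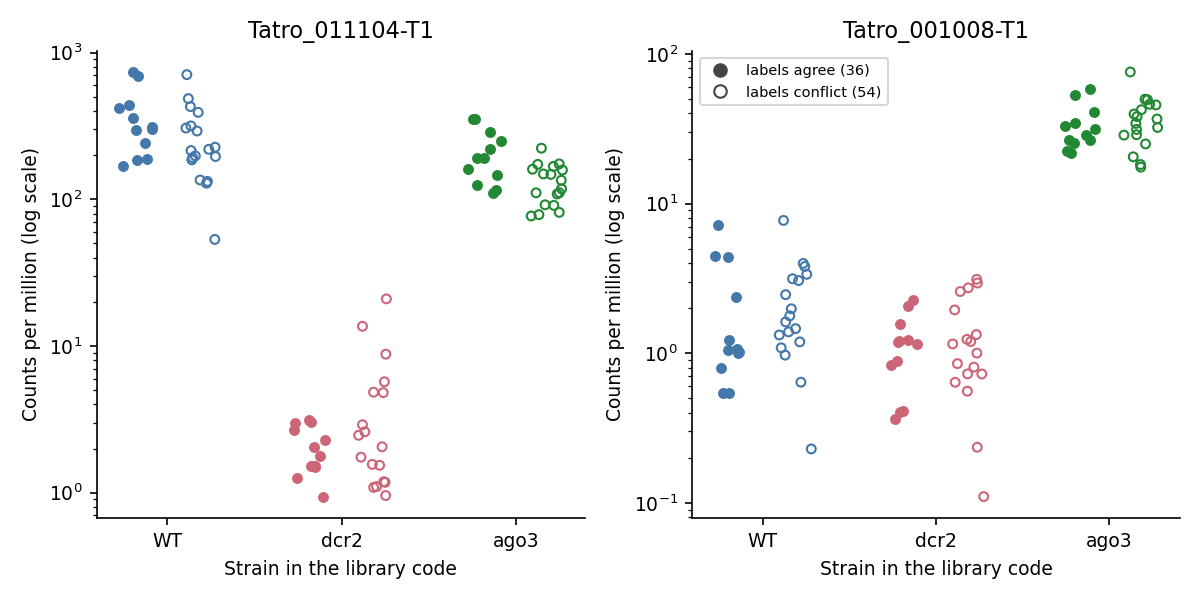
CPM (log axis) of Tatro_011104-T1 and Tatro_001008-T1 in each of the 90 libraries, arranged by the strain in the library code and marked by whether wording and code of the title matched. All 30 libraries coded dcr2 lie at or below 20.96 CPM of Tatro_011104-T1 and all 30 coded ago3 lie at or above 17.52 CPM of Tatro_001008-T1.

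Multidimensional scaling used, for each pair of libraries, the 500 transcripts with the largest fold changes between them. The first dimension carried 28.4% of the variance and the second 13.7%. Libraries coded dcr2 lay apart from those coded WT and ago3, except that dcr2 libraries with Alternaria before and at contact lay between them and ago3 replicates 2 and 3 with AG2 at contact were displaced towards dcr2.

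**Figure D2:**
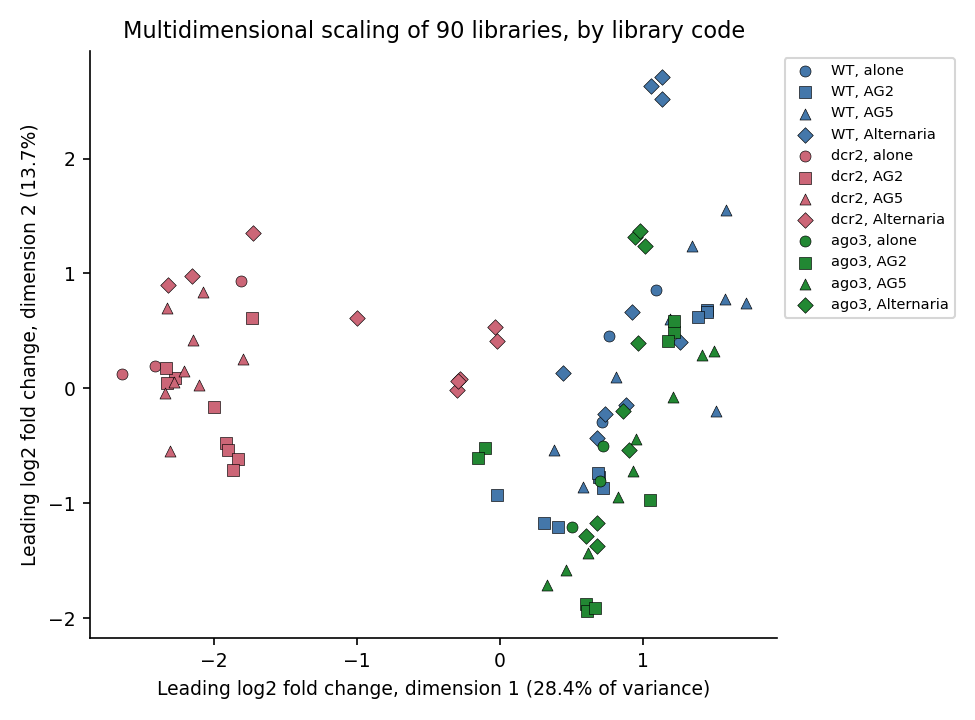
Multidimensional scaling of the 90 libraries on log2 CPM, from the 500 transcripts with the largest fold changes between each pair of libraries. The first dimension (28.4% of the variance) is on the horizontal axis and the second (13.7%) on the vertical axis. Each point is a library, coloured by the strain and shaped by the prey in its library code.

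The first comparison asked what the dcr2 mutation changed without prey. Tatro_008132-T1 rose from 18.1 ± 14.9 CPM in WT controls to 2011 ± 663 CPM in dcr2 controls (SD, n = 3), a log2 fold change of 6.79 ± 0.95 (SE). Tatro_001444-T1 rose from 33.6 ± 24.6 to 3069 ± 1917 CPM, a log2 fold change of 6.51 ± 0.92. Tatro_002651-T1 fell from 38.9 ± 31.7 CPM to 1 count over the 3 dcr2 libraries, a ratio of 1000 with a 95% counting interval of 179.5 to 39510. Tatro_010179-T1 stood at 10.2 ± 12.97 CPM in WT and had no count in dcr2, at least 87.4-fold lower against a floor of 3 counts over the group. For these 4 transcripts edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 4.64e-08, 5.88e-08, 3.64e-08 and 1.79e-07, and all 3 libraries of one strain lay above all 3 of the other, as for every transcript named in the control and single-stage comparisons except where stated. Altogether 2010 of 10843 transcripts differed, 657 higher and 1353 lower in dcr2. Intervals and floors cover counting error only.

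The same question for ago3 gave 558 transcripts, 177 higher and 381 lower than in WT controls. Tatro_009148-T1 rose from 0.212 ± 0.366 to 13.5 ± 3.75 CPM (log2 fold change 5.84 ± 0.90) and Tatro_004681-T1 from 2.33 ± 0.80 to 47.6 ± 31.03 CPM (4.35 ± 0.71). Tatro_004797-T1 and Tatro_008074-T1 had no count in the ago3 controls against 30.9 ± 52.96 and 9.18 ± 14.3 CPM in WT, at least 277.5-fold and at least 82.4-fold lower. Adjusted p was 8.11e-06, 2.23e-05, 0.00207 and 0.00124 in that order by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without WT control replicate 1 the count fell to 320, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.357 for Tatro_004797-T1 (0.000656 to 0.43 over the alternatives) and 0.0921 for Tatro_008074-T1 (0.000126 to 0.233), which ended both calls. It was 361 without WT control replicate 2, and with the spread estimated from the 6 control libraries alone it was 83.

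The 2 mutants' differences from WT overlapped: 227 transcripts differed in the same direction in both, 39 higher and 188 lower, and 69 in opposite directions. Independent lists of these sizes would share 58.3 in the same direction. Because both comparisons used the same WT controls, unchanged groups were simulated against them 20 times. At most 1 transcript was called in a simulated comparison, so the simulations gave no overlap of calls to set beside the 227. The covariance of the log2 fold changes across transcripts, which are not independent replicates, was 0.466, against a simulated median of 0.0887 and a highest of 0.107, and the correlation was 0.363 against a simulated median of 0.492. The simulations used the spread shared by all groups, and the WT control replicates differed more than most, so the simulated covariance may be too low. With 3 control libraries the controls could not be split, so part of the excess may come from the shared controls. The overlap was 124 without WT control replicate 1, 359 without WT control replicate 3 and 37 with the spread estimated from the controls alone.

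Most transcripts called between WT with AG2 before contact and WT grown alone were lower with AG2. Of 915 transcripts that differed from WT grown alone, 156 rose and 759 fell. Tatro_006444-T1 rose from 11.6 ± 8.51 to 75.9 ± 9.74 CPM (log2 fold change 2.70 ± 0.61) and Tatro_007675-T1 from 0.368 ± 0.141 to 5.38 ± 2.15 CPM (3.81 ± 0.96). Tatro_004123-T1 fell from 514.7 ± 837.7 to 2.61 ± 1.25 CPM (-7.64 ± 1.58), and Tatro_011619-T1 from 16.3 ± 27.5 CPM to 1 count, a ratio of 399.1 (95% counting interval 71.6 to 15770). In the same order, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00111, 0.00324, 0.000442 and 0.0075. WT control replicate 1 held the highest of the 3 control levels for 511 of the 759 transcripts that fell. Without it edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.076 for Tatro_004123-T1 (4.86e-08 to 0.076 over the alternatives) and 0.42 for Tatro_011619-T1 (0.0037 to 0.42), which ended both calls. With the spread estimated from the 6 libraries alone 525 transcripts differed and Tatro_004123-T1 lost its call, as Tatro_011619-T1 did under DESeq2. Tatro_007675-T1 lost its call without replicate 1 of every group. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0674.

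At contact with AG2, 540 transcripts differed from WT grown alone, 85 higher and 455 lower. Tatro_002949-T1 rose from 0.341 ± 0.114 to 42.4 ± 48.5 CPM (log2 fold change 6.92 ± 1.87) and Tatro_011598-T1 from 1.72 ± 0.469 to 42.03 ± 39.7 CPM (4.61 ± 0.93). Tatro_010316-T1 had no count at contact against 18.2 ± 28.9 CPM in the controls, at least 186.7-fold lower, and Tatro_004797-T1 held 1 count, a ratio of 951.1 (95% counting interval 170.7 to 37570). For these, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0127, 0.00086, 0.000365 and 0.00423. Without WT control replicate 1 the count was 265, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0582 for Tatro_002949-T1 (0.000272 to 0.178 over the alternatives) and 0.509 for Tatro_004797-T1 (0.00144 to 0.617), which ended both calls. Without WT control replicate 2 it was 334 and the call of Tatro_002949-T1 ended, under DESeq2 that of Tatro_004797-T1 ended, and with the spread of the 6 libraries alone it was 220. Tatro_011598-T1 lost its call without replicate 3 of every group, and Tatro_010316-T1 without replicate 1. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0646 and 0.0553.

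After contact with AG2, 277 transcripts were higher and 228 lower than in WT grown alone. Tatro_011871-T1 had no count in the controls and reached 46.1 ± 13.2 CPM, at least 409.6-fold higher, and Tatro_002949-T1 rose from 0.341 ± 0.114 to 220.3 ± 140.3 CPM (log2 fold change 9.29 ± 1.93). Tatro_004797-T1 had no count after contact, at least 269.8-fold lower than in the controls, and Tatro_011619-T1 held 1 count, a ratio of 427.7 (95% counting interval 76.8 to 16890). With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 4.75e-08, 0.000683, 0.00216 and 0.0114. Without WT control replicate 1 the total of 505 fell to 326, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.317 for Tatro_004797-T1 (0.000942 to 0.427 over the alternatives) and 0.437 for Tatro_011619-T1 (0.00726 to 0.437), which ended both calls. DESeq2 also ended that of Tatro_011619-T1, and with the spread of the 6 libraries alone 289 differed. Tatro_002949-T1 lost its call without replicate 2 of every group. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0521. The plot of calls per comparison sets these counts beside those of the mutants.

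**Figure D3:**
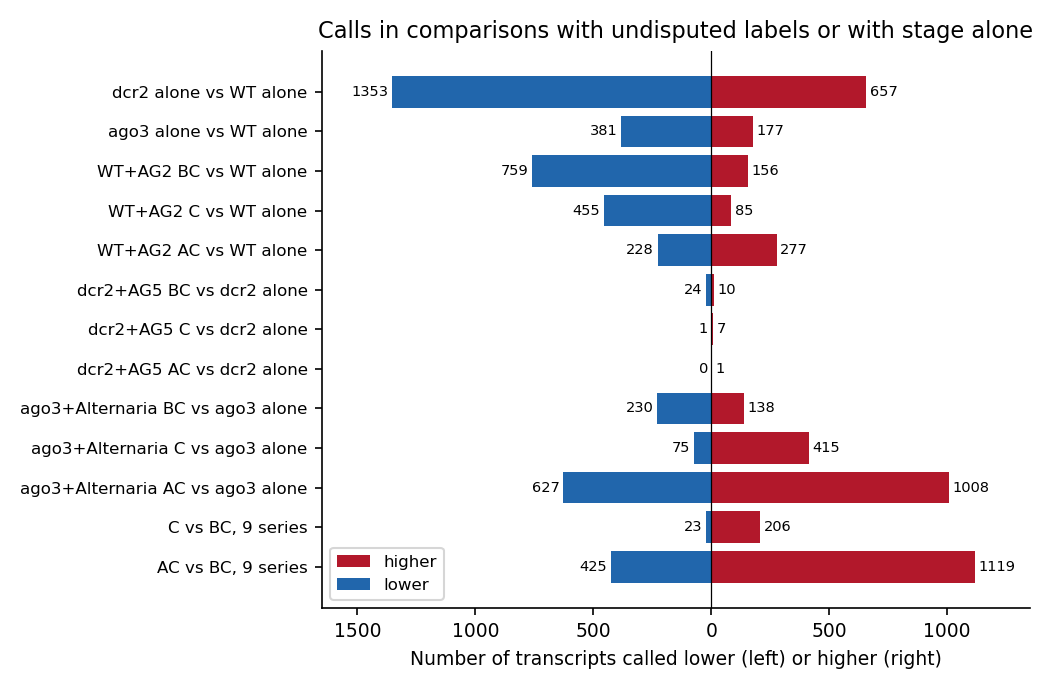
Number of transcripts called higher and lower in each comparison (edgeR's quasi-likelihood test, adjusted p below 0.05 and log2 fold change of at least 1), as bars from 0. The dcr2 controls against WT controls gave 2010 calls and ago3 with Alternaria after contact gave 1635, whereas dcr2 with AG5 gave 34, 8 and 1.

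Few transcripts differed between dcr2 with AG5 and dcr2 grown alone. Before contact 34 transcripts differed, 10 higher and 24 lower. Tatro_004685-T1 rose from 30.4 ± 12.9 to 88.5 ± 8.85 CPM (log2 fold change 1.54 ± 0.28) and Tatro_002818-T1 from 364.9 ± 138.9 to 984.9 ± 153.8 CPM (1.43 ± 0.36). Tatro_002544-T1 fell from 9.25 ± 5.88 to 0.517 ± 0.399 CPM (-4.09 ± 0.92) and Tatro_005350-T1 from 91.98 ± 63.2 to 11.97 ± 8.29 CPM (-2.96 ± 0.73). Adjusted p-values of these transcripts from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.000976, 0.0358, 0.0123 and 0.0322. At contact 7 transcripts were higher and 1 lower: Tatro_002142-T1 rose from 0.963 ± 0.651 to 10.5 ± 2.89 CPM (3.50 ± 0.66), Tatro_011626-T1 from 4.795 ± 1.49 to 23.96 ± 11.9 CPM (2.31 ± 0.45), and Tatro_011859-T1 fell from 47.9 ± 39.8 to 11.9 ± 4.24 CPM (-2.001 ± 0.44), with adjusted p = 0.00702, 0.00864 and 0.028 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. After contact the single call was Tatro_008692-T1, named after its values were seen and with overlapping groups, at 981.7 ± 553.6 against 276.7 ± 152.6 CPM (1.83 ± 0.34, adjusted p = 0.00852, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the spread of the 6 libraries alone the counts were 19, 0 and 0, and none of the 7 transcripts named before and at contact kept its call, whereas DESeq2 gave 56, 41 and 15, and 1175, 740 and 1193 transcripts had an unadjusted p below 0.05. Without any effect a share of 0.05 of the 10843 tested transcripts would have such a p, here and in such counts below. Single libraries decided the small counts: without dcr2 control replicate 2 the counts at and after contact were 2 and 0, without replicate 3 they were 18 and 28, and without replicate 1 the count after contact was 9. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, omitting dcr2 control replicate 1 ended the calls of Tatro_002818-T1, Tatro_005350-T1, Tatro_002142-T1 and Tatro_011859-T1 (adjusted p = 0.0644, 0.211, 0.064 and 0.691), and omitting replicate 2 those of Tatro_002818-T1, Tatro_002544-T1 and Tatro_011626-T1 (0.226, 0.0587 and 0.128), within ranges over the alternatives that reached from 2.63e-05 to 1.0 among them.

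In the ago3 mutant with Alternaria most calls came after contact. Before contact 368 transcripts differed from ago3 grown alone, 138 higher and 230 lower. Tatro_008395-T1 rose from 65.3 ± 12.2 to 1534 ± 109 CPM (log2 fold change 4.56 ± 0.34) and Tatro_001377-T1 from 3.53 ± 4.29 to 68.03 ± 27.2 CPM (4.30 ± 1.18). Tatro_010865-T1 fell from 27.0 ± 20.3 to 0.869 ± 0.640 CPM (-4.92 ± 1.06), and Tatro_004570-T1 from 7.02 ± 3.61 CPM to 1 count, a ratio of 173.6 (95% counting interval 31.2 to 6856). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 1.17e-16, 0.0165, 0.00204 and 0.000787. Tatro_010865-T1 lost its call without replicate 2 or 3 of every group. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0981 and 0.0672. Without ago3 control replicate 2 the count was 241 and without replicate 3 it was 236, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment either omission ended the call of Tatro_001377-T1 (adjusted p = 0.0985 and 0.11, in a range of 0.00217 to 0.215 over the alternatives).

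At contact with Alternaria 490 transcripts differed in ago3, 415 higher and 75 lower. Tatro_004737-T1 and Tatro_010145-T1 had no count in the ago3 controls and reached 16.5 ± 16.7 and 10.6 ± 11.8 CPM, at least 148.0-fold and at least 95.5-fold higher. Tatro_006494-T1 fell from 6.27 ± 5.49 to 0.129 ± 0.034 CPM (log2 fold change -5.43 ± 1.10) and Tatro_006627-T1 from 63.4 ± 26.9 to 2.86 ± 1.59 CPM (-4.47 ± 0.80). For these, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 4.22e-05, 2.08e-06, 0.000424 and 5.24e-05. The count was 282 without ago3 control replicate 1 and 261 with the spread of the 6 libraries alone. Tatro_006494-T1 lost its call without replicate 3 of every group. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.059.

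After contact with Alternaria 1635 transcripts differed in ago3, 1008 higher and 627 lower. Tatro_002863-T1 held 1 count in the controls and 24.01 ± 10.9 CPM after contact, a ratio of 646.9 (95% counting interval 116.1 to 25550). Tatro_008842-T1 rose from 0.533 ± 0.810 to 177.9 ± 64.9 CPM (log2 fold change 8.16 ± 0.76). Tatro_002464-T1 fell from 11.5 ± 6.34 to 0.267 ± 0.134 CPM (-5.35 ± 1.31) and Tatro_008054-T1 from 35.3 ± 17.1 to 1.31 ± 0.182 CPM (-4.71 ± 0.51). Adjusted p was 1.45e-05, 5.82e-13, 0.00126 and 7.3e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 505 transcripts that differed in WT after contact with AG2, 145 differed in the same direction in ago3 after contact with Alternaria and 30 in the opposite direction, where independent lists would share 38.9 in the same direction. These comparisons have no library in common, and strain and prey changed together between them.

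The stage comparisons asked what changed from before to after contact over the 9 series of strain and prey, and their outcome did not depend on the reading of the labels. No strain grown alone was sampled by stage, so contact cannot be told apart from time in culture here. At contact 206 transcripts were higher and 23 lower than before contact, and none separated the 27 libraries of a stage from the 27 of the other. Tatro_007203-T1 rose from 7.25 ± 6.86 to 66.4 ± 115.2 CPM (n = 27; log2 fold change 1.99 ± 0.22) and Tatro_011958-T1 fell from 124.4 ± 67.2 to 59.9 ± 35.3 CPM (-1.04 ± 0.11), both named after their values were seen. After contact 1119 were higher and 425 lower than before contact. Tatro_002578-T1 fell from 214.6 ± 70.8 to 41.8 ± 24.6 CPM (-2.69 ± 0.10) and Tatro_011385-T1 from 331.7 ± 138.7 to 62.6 ± 37.3 CPM (-2.58 ± 0.11), and in both every library after contact lay below every library before it. Tatro_006220-T1 rose from 28.2 ± 10.4 to 89.9 ± 36.4 CPM (1.64 ± 0.08) and was named after its values were seen. In the same order, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 5.25e-10 for Tatro_007203-T1, 5.56e-11 for Tatro_011958-T1, 6.44e-34 for Tatro_002578-T1, 2.25e-29 for Tatro_011385-T1 and 8.15e-28 for Tatro_006220-T1.

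The responses of WT to the other preys, averaged over the stages, rest on conflicting labels. By the library code WT with AG5 differed from WT alone in 57 transcripts, 33 higher and 24 lower. Tatro_011871-T1, without a count in the WT controls, reached 17.3 ± 23.7 CPM (n = 9), at least 153.4-fold higher, and Tatro_001634-T1 rose from 1 count to 6.15 ± 9.29 CPM, a ratio of 164.0 (95% counting interval 29.4 to 6476). With Alternaria 579 transcripts differed by the code, 218 higher and 361 lower. Tatro_008395-T1 rose from 13.1 ± 1.68 to 779.6 ± 510.6 CPM (log2 fold change 5.62 ± 0.35) and Tatro_007348-T1 from 0.710 ± 0.957 to 1229 ± 1854 CPM (6.53 ± 1.13). Tatro_005571-T1 fell from 23.98 ± 11.1 to 4.05 ± 4.26 CPM (-3.85 ± 0.47) and Tatro_010636-T1 from 81.8 ± 47.96 to 9.22 ± 7.54 CPM (-3.75 ± 0.38). With edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00151 for Tatro_011871-T1, 0.0126 for Tatro_001634-T1, 7.27e-21 for Tatro_008395-T1, 3.49e-05 for Tatro_007348-T1, 1.38e-08 for Tatro_005571-T1 and 4.78e-11 for Tatro_010636-T1. By the wording the counts were 2320 for AG5 (633 higher, 1687 lower) and 913 for Alternaria (293 higher, 620 lower). Without WT control replicate 1 the code counts were 12 and 319, and without replicate 3 that for AG5 was 91. Without WT control replicate 1 or 2 Tatro_001634-T1 lost its call (adjusted p = 0.124 and 0.102 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.00466 to 0.793 over the alternatives). Tatro_011871-T1 lost its call without replicate 2 or 3 of every group. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.117 and 0.0627. With the spread of the groups compared alone edgeR gave 0 calls for AG5, DESeq2 gave 70, and 1184 transcripts had an unadjusted p below 0.05.

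Tatro_008395-T1 followed the prey in the library code. It stood at or above 252.9 CPM in all 27 libraries coded Alternaria and at or below 132.9 CPM in the other 63, as the plot of this transcript by prey and stage shows, and the 18 conflicting libraries worded Alternaria held 28.6 to 132.9 CPM. Means in libraries coded Alternaria were 1152 ± 426 CPM before contact, 1195 ± 287 at contact and 547.1 ± 256.7 after contact (SD, n = 9 each), against 28.96 ± 30.3 in the 9 controls. The transcript was singled out after its values were seen.

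**Figure D4:**
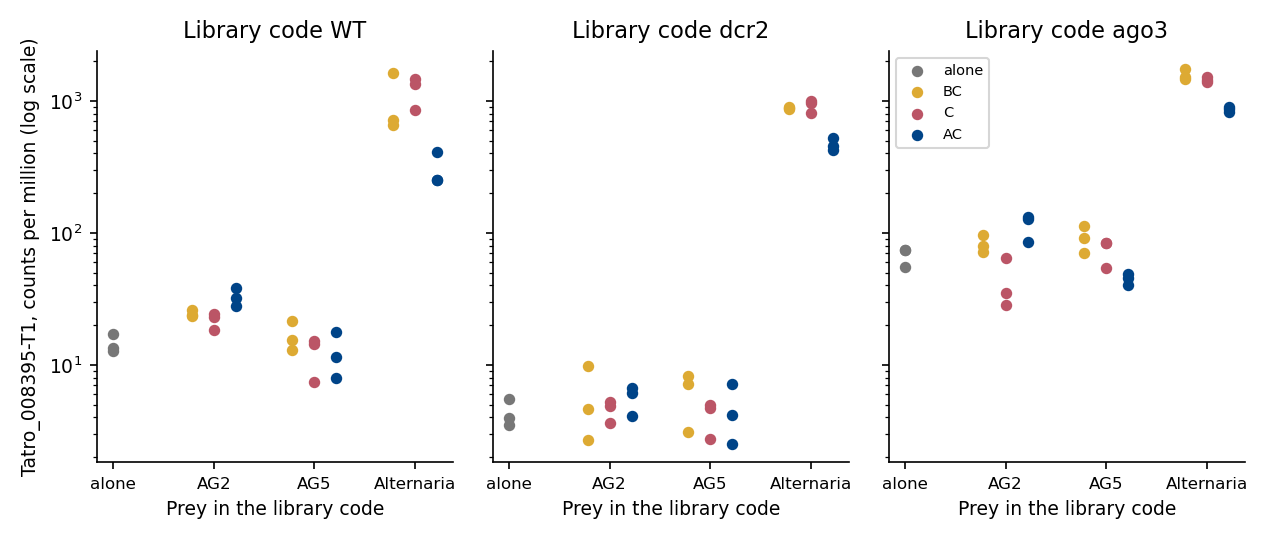
CPM (log axis) of Tatro_008395-T1 in each library by prey and stage, with a panel per strain. Strain and prey were taken from the library code, and colours show the stage. All 27 libraries coded Alternaria lie at or above 252.86 CPM and all 63 others at or below 132.92 CPM.

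The difference between dcr2 and WT was next taken in the presence of each prey, averaged over the stages. By the library code dcr2 differed from WT in 2031 transcripts with AG2 (722 higher, 1309 lower), 2585 with AG5 (812 higher, 1773 lower) and 1396 with Alternaria (464 higher, 932 lower). With AG2, Tatro_001344-T1 stood at 430.5 ± 189.8 against 4.15 ± 6.65 CPM (n = 9; log2 fold change 7.03 ± 0.50) and Tatro_011104-T1 at 2.66 ± 1.75 against 331.4 ± 166.4 CPM (-7.001 ± 0.36). With AG5, Tatro_008132-T1 stood at 2035 ± 734 against 21.5 ± 24.8 CPM (6.71 ± 0.55) and Tatro_010363-T1 at 0.0943 ± 0.124 against 10.6 ± 2.05 CPM (-7.29 ± 0.54). With Alternaria, Tatro_008393-T1 stood at 5078 ± 3039 against 142.9 ± 122.9 CPM (5.02 ± 0.47) and Tatro_010179-T1 at 0.0901 ± 0.164 against 7.97 ± 6.79 CPM (-6.77 ± 0.69). In that order edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 9.19e-19, 3.11e-25, 1.21e-16, 5.78e-19, 1.27e-13 and 2.01e-12. Of the 2010 transcripts that separated the controls, 1305 differed in the same direction with AG2, 1633 with AG5 and 804 with Alternaria, where independent lists would share 207.1, 270.4 and 144.4. The same 260 transcripts were higher and the same 393 lower in dcr2 in all 4 settings. In the 6 dcr2 libraries with Alternaria before and at contact, transcripts low in dcr2 controls and high in WT with Alternaria stood at medians of 0.245 to 0.715 of the way from the dcr2 control level to the WT level, against at most 0.023 after contact. Transcripts that Alternaria raises in both strains also count here, so these medians do not separate nearness to WT from a response to the prey. After contact alone, with these 6 libraries left out of the fit, dcr2 differed from WT with Alternaria in 3206 transcripts, 1342 higher and 1864 lower, of which 1185 were among the 1396. By the wording the counts were 471, 185 and 91, of which 29, 75 and 13 shared direction with the control difference and 178, 15 and 45 went in the opposite direction, where independent lists would share 32.5, 15.7 and 9.7 in the same direction. Without the shallow library and the 2 displaced ago3 libraries the worded count with Alternaria was 13.

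For ago3 against WT by the library code, 630 transcripts differed with AG2 (390 higher, 240 lower), 1035 with AG5 (355 higher, 680 lower) and 1017 with Alternaria (537 higher, 480 lower). The ago3 libraries with AG2 include replicates 2 and 3 at contact. There 52 transcripts high in dcr2 stood at medians of 0.263 and 0.242 of the way to the dcr2 level. Without these libraries and the shallow library the 3 counts stayed within 1.5 times. Tatro_009148-T1, which was higher in the ago3 controls, was also higher with AG2 (8.16 ± 4.52 against 0.0643 ± 0.0811 CPM, log2 fold change 7.03 ± 0.64) and with AG5 (7.38 ± 4.85 against 0.0523 ± 0.0633 CPM, 6.70 ± 0.63). With Alternaria it stood at 9.05 ± 4.53 CPM against 3 counts over the 9 WT libraries, a ratio of 245.4 (95% counting interval 83.97 to 1190). Tatro_000633-T1 was higher with AG2 (5.39 ± 0.62), AG5 (5.48 ± 0.67) and Alternaria (5.93 ± 0.71). Tatro_007043-T1 was lower with AG2, at 1.83 ± 0.719 against 274.3 ± 187.1 CPM (-6.92 ± 0.58), and with Alternaria, at 2.24 ± 0.894 against 191.1 ± 121.9 CPM (-6.14 ± 0.56). Tatro_000618-T1 was lower with AG5, at 0.327 ± 0.243 against 25.1 ± 15.2 CPM (-6.20 ± 0.59). The highest adjusted p among these from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.41e-09. Of the 558 transcripts that separated the controls, 154 differed in the same direction with AG2, 318 with AG5 and 231 with Alternaria, where independent lists would share 14.8, 29.7 and 25.6. The same 55 were higher and the same 58 lower in ago3 in all 4 settings. By the wording the counts were 793, 931 and 364, and that with AG5 was 251 without the 6 libraries coded dcr2 with Alternaria before and at contact, which are worded ago3 with AG5.

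The last comparisons asked whether a mutant responded to prey differently from WT, as the mean of the 9 confronted groups minus the control, in the mutant minus in WT. By the library code 38 transcripts differed for dcr2, 35 higher and 3 lower. Tatro_001070-T1 went from 8.79 ± 9.93 to 160.6 ± 294.7 CPM in dcr2 and from 292.7 ± 235.3 to 167.0 ± 113.8 CPM in WT (n = 3 controls and 27 confronted libraries; difference in log2 response 3.39 ± 0.71). Tatro_011946-T1 went from 2.27 ± 0.577 to 31.7 ± 46.5 CPM in dcr2 and from 82.4 ± 40.5 to 86.5 ± 71.9 CPM in WT (3.18 ± 0.62). The confronted dcr2 libraries include the 6 with Alternaria before and at contact. There, transcripts low in dcr2 controls and high in WT with Alternaria stood at medians of 0.245 to 0.715 of the way to that WT level. These medians may include a response to the prey. In the 21 confronted dcr2 libraries other than these, Tatro_001070-T1 stood at 19.1 ± 11.9 CPM and Tatro_011946-T1 at 10.05 ± 5.70 CPM. Without the 6 libraries and the WT groups of the same prey and stages 17 transcripts differed, 14 higher and 3 lower, of which 16 were among the 38, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the calls of Tatro_001070-T1 and Tatro_002603-T1 ended (adjusted p = 0.164 and 0.0941). The 3 lower ones were Tatro_004594-T1 (-3.30 ± 0.73), Tatro_002603-T1 (-1.96 ± 0.47) and Tatro_003816-T1 (-1.77 ± 0.40), the last named after its values were seen. For these 5, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.00653, 0.00273, 0.0132, 0.031 and 0.0146. The count was 17 with the spread of the groups compared alone and 99 under DESeq2, 75 without WT control replicate 3, and 74 and 11 without dcr2 control replicates 1 and 2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment single controls ended calls: adjusted p = 0.0757, 0.116 and 0.0743 for Tatro_001070-T1 without WT replicate 1 and dcr2 replicates 2 and 3, 0.0774 and 0.067 for Tatro_004594-T1 without WT replicate 2 and dcr2 replicate 3, and 0.189, 0.0945 and 0.201 for Tatro_002603-T1 without WT replicate 2 and dcr2 replicates 1 and 2, in ranges over the alternatives of 0.000106 to 0.223, 0.00199 to 0.454 and 0.00438 to 0.759. Tatro_011946-T1 lost its call without replicate 2 or 3 of every group. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.117 and 0.0983. The wording gave 2181 transcripts, 1451 higher and 730 lower.

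For ago3 116 transcripts responded differently from WT by the library code, 97 higher and 19 lower. Tatro_001782-T1 went from 3.51 ± 2.02 to 6.33 ± 2.29 CPM in ago3 and from 68.6 ± 105.7 to 7.88 ± 9.45 CPM in WT (4.18 ± 0.75), and Tatro_011617-T1 from 0.530 ± 0.528 to 1.06 ± 0.723 CPM in ago3 and from 62.5 ± 97.2 to 8.68 ± 19.6 CPM in WT (5.30 ± 1.31). Tatro_002951-T1 went from 83 ± 25.1 to 9.44 ± 12.2 CPM in ago3 and from 19.9 ± 13.03 to 14.7 ± 6.96 CPM in WT (-3.27 ± 0.64), and Tatro_000618-T1 from 7.50 ± 10.4 to 1.12 ± 1.84 CPM in ago3 and from 18.7 ± 16.99 to 27.8 ± 28.7 CPM in WT (-3.70 ± 0.80). Adjusted p-values of these transcripts from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 0.000786, 0.0211, 0.0028 and 0.00772. The count rested on single control libraries: it was 21, 67 and 330 without WT control replicates 1, 2 and 3, and 40, 45 and 64 without ago3 control replicates 1, 2 and 3, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Tatro_001782-T1 had adjusted p = 0.685 without WT control replicate 1 (6.02e-07 to 0.849 over the alternatives). Tatro_011617-T1 lost its call without WT control replicate 1 or ago3 control replicate 1 or 2, and Tatro_000618-T1 without WT or ago3 control replicate 2, with highest adjusted p = 1.0 and 0.837 over the alternatives by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tatro_002951-T1 lost its call without replicate 1 or 2 of every group. There edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.102 and 0.189. DESeq2 gave 191, and the wording gave 1260 transcripts, 890 higher and 370 lower.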

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

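The tests of mixed RNA, of mislabelled libraries and of other splits of the libraries were chosen after the results they test had been seen, and so were the comparisons of dcr2 with WT at single stages with Alternaria, the difference of differences before contact, the responses of WT with AG2 and of both mutants averaged over stages, and the fit without dcr2 with Alternaria before and at contact. Every library count below follows the library code unless the wording is named.

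Tests of the difference itself called transcripts whose response to prey differed between mutant and WT. For dcr2 the count was 38 by the library code, 35 of them higher, and 17 without the 6 libraries with Alternaria before and at contact, whose median apparent WT shares were 0.245 to 0.715. Such shares may include a response to the prey common to both strains. For ago3 the count was 116 by the code. By the wording the counts were 2181 for dcr2 and 1260 for ago3, which rest on labels that Tatro_011104-T1 and Tatro_001008-T1 contradicted in 35 and 36 of the 54 conflicting libraries. The difference between dcr2 and WT with Alternaria before contact, which rests on 3 of the 6 libraries, also differed from that between the controls, for 1263 transcripts, 727 higher and 536 lower. Tatro_001505-T1 stood at 42.2 ± 9.23 CPM in dcr2 with Alternaria before contact, 0.119 ± 0.0207 CPM in dcr2 controls, 11.3 ± 6.61 CPM in WT with Alternaria and 48.04 ± 38.1 CPM in WT controls (SD, n = 3; log2 difference 10.43 ± 1.70), with adjusted p = 1e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the strains exchanged within prey and stage in other ways, 1 of 21 splits gave as many calls as the real one for each response difference, the real one: 17 against at most 3 for dcr2 and 168 against at most 16 for ago3 by the code, and 2135 against at most 47 and 1347 against at most 239 by the wording. Exchanging the strains puts the difference between them into the spread within groups, which lowers the calls of the other splits. Their low counts therefore do not decide whether the responses differed. For the difference before contact with Alternaria, 9 of 100 splits gave at least the real 815 calls and the highest other gave 1048, so chance was not excluded by this count. The 8 others as large kept the strains whole in a single pair of groups, and the 80 splits that mixed the strains in both pairs gave at most 0 calls by edgeR, so the large splits point to a structure of the samples, the strain difference itself.

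With Alternaria, 774 transcripts differed between dcr2 and WT before contact and 260 at contact, against 3218 after contact and 2010 in the controls, and Tatro_001444-T1 stood at 546.4 ± 35.8 CPM in dcr2 before contact with Alternaria and at 3069 ± 1917 CPM in dcr2 controls. A mislabelled WT or ago3 library is argued against, because Tatro_011104-T1 reached at most 20.96 CPM in the 6 dcr2 libraries and at least 53.29 CPM in every WT and ago3 library. WT RNA mixed into the dcr2 libraries could not be excluded: the apparent WT share had medians of 0.595 (quartiles 0.407 to 0.894), 0.586 (0.345 to 0.916) and 0.637 (0.402 to 0.904) before contact and 0.245 (0.139 to 0.404), 0.715 (0.436 to 1.041) and 0.649 (0.405 to 0.812) at contact, with a quartile over 0.2 from the median in 5 of 6 libraries and thus no single sharp share, but this was so in 6 of 6 WT libraries set against the other WT libraries of their stage, by 0.212 to 0.503. The share was taken from dcr2 grown alone towards WT with Alternaria. Transcripts that Alternaria raises in both strains thus count towards it, and it cannot tell mixing from a response to the prey. Under 1/3 of the median lay 8.0%, 8.0% and 7.0% of transcripts before and 13.4%, 9.4% and 10.7% at contact (0.7% to 3.5% in the WT libraries). Mixing required under 10% in each library and exclusion 25%, so these values did not decide. Against mixing, Tatro_011104-T1 stood at 4.84, 4.81 and 8.80 CPM before and 1.09, 13.64 and 20.96 CPM at contact. The shares above would bring 163.5, 160.9, 174.8, 114.6, 334.8 and 303.8 CPM from WT of that stage. From the WT library lowest in it they would bring 31.7, 31.2, 33.9, 13.04, 38.1 and 34.6 CPM. Shares that include a response to the prey would make these levels too high, and a single transcript does not exclude mixing. A change of the dcr2 mutant facing Alternaria, the biological explanation that the design offers, remains open and was not tested.

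Replicates 2 and 3 of ago3 with AG2 at contact carried transcripts that are high in dcr2. Over 52 such transcripts the apparent dcr2 share had medians of 0.263 and 0.242 in these libraries, -0.018 in replicate 1 of the same group, while the 28 ago3 libraries other than these ranged from -0.025 to 0.053. A mislabelled dcr2 library is argued against, because the lower of both libraries held 17.52 CPM of Tatro_001008-T1 and no dcr2 library held more than 3.12 CPM. RNA of the dcr2 strain mixed in may account for the pattern, since the quartiles of the share lay within 0.077 of its median in both libraries. No biological explanation was tested, because the design gives these replicates no difference.

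Transcripts with adjacent identifier numbers changed together. Between dcr2 and WT controls 444 adjacent pairs were called in the same direction, against a mean of 187.4 and at most 234 over 10000 shufflings (one-sided permutation p = 0.0001, the smallest that they can give). The ratio of observed to shuffled pairs was 2.37 and stayed at 2.23 without models with a fractional value, so reads shared between adjacent models are argued against as the cause. The ratio was 5.01 for ago3 controls, 3.02 for WT with AG2 before contact and 2.78 for ago3 with Alternaria after contact. Neighbouring genes that change as blocks may be a candidate explanation of the 444 pairs, but whether the numbers follow genome position is not known here.

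The counts of calls were set against other splits of the same libraries, fitted to the groups compared alone. With 3 libraries against 3 the 10 splits are too few for a share under 0.05, and the real split was the only 1 as large in these: 1354 calls for dcr2 and 83 for ago3 controls, 525, 220 and 289 for WT with AG2, 19 for dcr2 with AG5 before contact, 473, 261 and 1703 for ago3 with Alternaria, and 645, 96 and 3116 for dcr2 against WT with Alternaria, each at the stages in order. The highest other split gave 0 calls by edgeR in all of these except 1 for dcr2 with AG5 before contact. For dcr2 with AG5 at and after contact edgeR gave 0 calls in the real split, where DESeq2 gave 41 and 15 and 740 and 1193 transcripts had an unadjusted p below 0.05, so 10 of 10 splits were as large and the highest others gave 12 and 16.

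By the library code, with 25 splits, 1 split was as large, the real one, in each of these: WT with Alternaria (416 calls, highest other 0), dcr2 against WT with AG2 (1925, 626), AG5 (2357, 1286) and Alternaria (1316, 0), and ago3 against WT with AG2 (659, 66), AG5 (920, 0) and Alternaria (968, 235). The smallest share that 25 splits can give is 1 of 25, and no adjustment was made over the comparisons. Regrouping also mixes unlike libraries, which widens the spread and tends to lower the calls of the other splits. These counts therefore do not exclude chance. WT with AG5 gave 0 calls by edgeR (70 by DESeq2 with all groups, 1184 at an unadjusted p below 0.05) and so 25 of 25 splits were as large, with a highest other of 0. By the wording 1 of 25 was as large for WT with AG5 (1956, 155), dcr2 against WT with AG2 (355, 2), AG5 (141, 4) and Alternaria (105, 49), and ago3 against WT with AG2 (790, 259), AG5 (809, 0) and Alternaria (379, 53). For WT with Alternaria by the wording 2 of 25 were as large (843, 1048), so chance was not excluded there either. For the stages 1 of 21 splits was as large, at contact (211, 1) and after contact (1529, 18).

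Among the responses averaged over stages, 1 of 25 splits was as large for WT with AG2 (396 calls, highest other 0), dcr2 with AG2 (110, 2), dcr2 with Alternaria (683, 622) and ago3 with AG5 (313, 49). By these counts chance was not excluded for any of the responses. Other splits were also as large as the real one for dcr2 with AG5 (2 of 25 splits, 1 and 2 calls), ago3 with AG2 (3 of 25, 270 and 1651) and ago3 with Alternaria (2 of 25, 480 and 1538). Splits with 1651 and 1538 calls, several times the real count, point to a structure of these samples other than confrontation against control.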

How the results depend on the processing

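The summing of transcript models, the fits without the shallow library and both displaced ago3 libraries or without dcr2 with Alternaria before and at contact, and the omission of single control libraries were chosen after the data had been seen, and the cause of each change below was not tested, except that fits with fewer libraries have less information. Over 1602 values of 120 named results under 20 alternatives, 1443 kept direction and call, 159 kept only direction and 0 reversed. The naming rule chose the largest called changes, outside the response differences only between groups that did not overlap. A reversal was therefore unlikely from the start, and its absence says little about other transcripts. Counts stayed within 1.5 times without a low-count filter and with models summed per gene. With the spread of the groups compared alone they were 83 for ago3 controls, 525, 220 and 289 for WT with AG2, 19, 0 and 0 for dcr2 with AG5, 261 for ago3 with Alternaria at contact, 0 for WT with AG5 and 17 for the dcr2 response difference by the code, 110 for dcr2 with AG2, 1 for dcr2 with AG5 over the stages, 96 for dcr2 against WT with Alternaria at contact, 815 for the difference of differences before contact and 37 for the overlap of both mutants. Where edgeR gave 0 for dcr2 with AG5 at and after contact and for WT with AG5, DESeq2 with all groups gave 41, 15 and 70, and 740, 1193 and 1184 transcripts had an unadjusted p below 0.05. DESeq2 gave 56, 41 and 15 for dcr2 with AG5 by stage and 29 over the stages, 99 for the dcr2 and 191 for the ago3 response difference. RLE factors gave 2 for dcr2 with AG5 after contact and took the median log2 fold change of dcr2 against WT with Alternaria after contact from -0.031 to -0.114. The replicate block gave 53 and 5 for dcr2 with AG5 before and after contact, where the numbers did not pair the samples, and 2031 for dcr2 against WT controls, of which 1976 were the same transcripts. Without the 3 odd libraries dcr2 against WT with Alternaria by the wording gave 13. Without dcr2 with Alternaria before and at contact and the matching groups, counts were 3206 for dcr2 against WT with Alternaria, 17 for the dcr2 response difference and 233 for dcr2 with Alternaria by the code, and 251 for ago3 against WT with AG5 by the wording, and the comparisons of these stages themselves gave no value. Leaving out replicates or single controls, counts ranged over 178 to 829 for ago3 controls, 296 to 1241, 56 to 744 and 211 to 547 for WT with AG2 by stage, 6 to 58, 0 to 18 and 0 to 28 for dcr2 with AG5, and 63 to 391, 160 to 474 and 1068 to 1637 for ago3 with Alternaria. By the code they ranged over 3 to 91 for WT with AG5, 301 to 671 for WT with Alternaria, and 6 to 75 and 4 to 330 for the dcr2 and ago3 response differences. By the wording they ranged over 510 to 1036 for WT with Alternaria, 180 to 557, 79 to 127 and 17 to 97 for dcr2 against WT with AG2, AG5 and Alternaria, and 701 to 1471 for the ago3 response difference. Over the stages they ranged over 105 to 659 for WT with AG2, 90 to 286, 3 to 38 and 416 to 886 for dcr2 with AG2, AG5 and Alternaria, and 60 to 147, 140 to 178 and 189 to 410 for ago3 with the same preys. For dcr2 against WT with Alternaria the range was 367 to 793 before and 65 to 295 at contact, 784 to 1408 for the difference of differences and 75 to 359 for the overlap. Ranges within 1.5 times were 1425 to 2100 for dcr2 controls, 162 to 244 and 1365 to 1540 for the stages at and after contact, and 1845 to 1975, 2331 to 2617 and 1107 to 1370 for dcr2 against WT by the code. Gene list tests and their alternative correlation were not run.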

Other observations

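The comparisons in this part were all chosen after the data had been seen and follow the library code.

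Averaged over the stages, Tatro_008395-T1 and Tatro_004544-T1 were raised with Alternaria in the mutants. In ago3 462 transcripts differed from ago3 grown alone, 310 higher and 152 lower. In dcr2 850 differed from dcr2 grown alone, 519 higher and 331 lower. However, 6 of the 9 libraries, those before and at contact, had median apparent WT shares of 0.245 to 0.715, which may include the response to Alternaria. After contact alone, without these 6, 233 transcripts differed in dcr2, 168 higher and 65 lower, of which 129 were among the 850, and Tatro_008395-T1 and Tatro_004544-T1 kept their calls. Tatro_008395-T1 rose from 4.88 ± 1.01 CPM (SD, n = 3) to 845.9 ± 251.7 CPM (n = 9) in dcr2, a log2 fold change of 7.37 ± 0.38, and Tatro_004544-T1 from 7.12 ± 3.63 to 713.6 ± 584.6 CPM in dcr2 (6.03 ± 0.59) and from 6.22 ± 2.28 to 1136 ± 1250 CPM in ago3 (6.35 ± 0.60). Tatro_006627-T1 fell in ago3 from 63.4 ± 26.9 to 2.96 ± 1.28 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.64e-25, 4.15e-12, 2.81e-12 and 4.53e-09, and every confronted library lay beyond every control. The count for ago3 was 234 without ago3 control replicate 1.

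With R. solani the counts were 442 for WT with AG2 (38 higher, 404 lower), 229 for dcr2 with AG2 (67, 162), 13 for dcr2 with AG5 (2, 11), 202 for ago3 with AG2 (116, 86) and 255 for ago3 with AG5 (147, 108). The ago3 libraries with AG2 include replicates 2 and 3 at contact, with median apparent dcr2 shares of 0.263 and 0.242. Tatro_002951-T1 fell in ago3 from 83 ± 25.1 CPM to 16.8 ± 18.8 CPM with AG2 and 6.29 ± 5.63 CPM with AG5 (log2 fold changes -3.12 and -4.21). Tatro_002353-T1 fell in dcr2 with AG2 from 87.3 ± 114.0 to 2.06 ± 2.02 CPM (-5.74). Both transcripts higher in dcr2 with AG5 were Tatro_004685-T1, at 71.5 ± 21.8 against 30.4 ± 12.9 CPM (1.18), and Tatro_008692-T1, at 901.3 ± 324.1 against 276.7 ± 152.6 CPM (1.69), both named after their values were seen and with overlapping groups. Adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 1.76e-06, 4.68e-10, 1.17e-09, 0.00967 and 0.00157. Counts without single controls were 105 for WT with AG2 (WT replicate 1), 90 for dcr2 with AG2 (dcr2 replicate 1), 3, 24 and 38 for dcr2 with AG5 (dcr2 replicates 1, 2 and 3), 118, 126 and 112 for ago3 with AG2 (ago3 replicates 1, 2 and 3) and 151 for ago3 with AG5 (ago3 replicate 1).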
